A study of Homo sapiens with 25 samples.

How the data were processed

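The deposited table held log2 values of 20220 probe sets on 25 arrays, summarised and scaled between arrays by the authors, whose processing notes name MAS5 without version or settings. The full method behind the deposited log2 values, and how far MAS5 explains them, is not given in the sources used here. The values ran from 2.55 to 14.71, and the medians of the arrays differed by 0.1711 at most, so they were used as deposited. Per the labels, RNA integrity was checked on a bioanalyzer.

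Of the probe sets, 17537 carried the name of a single gene, of which 17526 were matched by their gene number. Probe sets with several genes (972), without a name (1711) and for Y-linked genes or XIST (26) were left out, which left 17511. Each gene was represented by its probe set with the highest mean over all arrays, a choice needed for 3931 of 11228 genes. The 25% of genes with the lowest mean were left out, and 8421 were tested. Control probe sets were 0 in number, so RNA degradation measures from them were not used here.

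Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with group means as coefficients. Comparisons within a cell type used all 14 AT2 or all 11 MSC arrays, and the comparison of responses and that of controls used all 25. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called changed below an adjusted p of 0.05. Errors printed with changes are standard errors from this fit, and errors printed with means are standard deviations. Gene lists with at least 5 tested genes were tested with camera at its preset correlation, adjusted over the lists of each comparison, with an estimated correlation and with fry beside it. Of 192 tests of a list in a comparison, 98 were past the threshold, and 22 were with an estimated correlation. Permutation tests of array quality were exact and two-sided, in scipy 1.17.1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

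The groups, the comparisons, the model, the threshold, the 24 lists with 833 genes (717 with a probe set) and the alternatives, except those said to be added later, were chosen before the data were examined. The lists cover interferon-inducible genes, antigen processing and presentation, chemokines, cytokines and growth factors of inflammation, and NF-kappaB targets and feedback regulators. They also cover complement, acute phase and antimicrobial genes, alveolar type II and surfactant genes, alveolar type I genes, ion and fluid transport, tight and adherens junctions, eicosanoid synthesis and receptors, and secreted mediators attributed to MSCs. Markers of mesenchymal stromal, epithelial, macrophage and leukocyte, endothelial and airway epithelial cells made up 5 lists. Cell cycle, cholesterol and fatty acid synthesis, glycolysis and hypoxia, matrix and proteases, cell death, oxidative stress and nitric oxide, and stress response and unfolded protein genes made up the rest.

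Genes were named by a rule written beforehand. It takes the 8 largest rises and the 8 largest falls past the threshold in each comparison within a cell type, 5 of each in the other comparisons, and up to 4 members of each list past the threshold with the largest change. It adds the 8 genes with the largest product of opposite changes and 35 fixed genes, of which 31 were analysed here. Means of SLC39A8, MEST and other named genes in further groups are of the same probe sets.

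Replicate numbers of the AT2 groups were tested for pairing from the data, since the labels do not state it. The 13 pairs of AT2 arrays with the same number in different groups correlated across genes at 0.149 to 0.487 after group means were removed (median 0.366, against -0.154 for other pairs). Some pairs of different numbers correlated as well, such as control 5 with cytomix 1 at 0.441, where control 1 with cytomix 1 had 0.149, and control 2 with cytomix 3 at 0.479, and 17 of 26 comparisons were highest for the own number. As every pair of the same number was above 0.1, a fit with the number as a block is given where it changes a call. Alternatives tried were quantile normalisation, a shift to a common 75th percentile, no filter, a filter on the lower 50%, the mean over probe sets, eBayes without trend, robust eBayes, array weights, a 2-fold minimum, an adjusted p of 0.01, the block, fits on other sets of arrays, and leaving out each array. Averaging arrays 2 and 3 of the AT2 groups, and lists and named genes without AT2 cytomix 1 or array 5 of AT2 cytomix with MSCs, were added after the data were seen. An offset before the logarithm was not used here because the table already held logarithms.

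The share of MSC RNA in an AT2 array was worked out for genes with a log2 mean of at least 11 in MSC transwell and at most 6 in AT2 arrays without MSCs. It is the excess over those AT2 arrays on the linear scale, in percent of the difference between MSC transwell and those AT2 arrays. Other splits of the arrays were counted in full or, above 100, drawn with seed 300.

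The code was tested on simulated normal data with the spread of each gene and 200 changed genes among 8421. Of 100 genes changed by a log2 of 1, it recovered 74 in AT2 cytomix against AT2 control, 69 in AT2 cytomix with MSCs against AT2 cytomix and 66 against AT2 control. It recovered 54 in MSC cytomix against MSC control, 67 in MSC transwell against MSC control, 54 against MSC cytomix, 45 for the difference of responses and 72 for the controls. Of 100 changed by a log2 of 2 it recovered 91, 94, 90, 90, 92, 90, 83 and 94 in the same order, with 4 to 13 false calls. The list that was shifted was called in each comparison and 0 others were. The simulated genes and arrays were independent of each other. False calls from correlated genes, or from arrays that are close to each other, could therefore not show.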

Results

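Gene expression was measured on 25 Affymetrix GeneChip arrays of primary human alveolar type II (AT2) cells, the surfactant-making cells of the distal lung, and of human mesenchymal stem cells (MSCs), which are multipotent stromal cells. Per the labels, AT2 cells grew as a monolayer for 96 to 120 h and then spent 24 h in serum-free medium. MSCs, 250000 per well, were placed in the lower compartment of a transwell, a porous insert that lets the layers share medium without touching. Injury was modelled with cytomix, a mixture of interleukin 1 beta, tumour necrosis factor alpha and interferon gamma at 50 ng/ml each. The groups were AT2 control (n = 5), AT2 cytomix (n = 4), AT2 cytomix with MSCs (n = 5), MSC control (n = 3), MSC cytomix (n = 3) and MSC transwell, the MSCs taken from co-culture (n = 5). The titles of the MSC transwell arrays do not name cytomix, and the treatment protocol states that co-cultured cells received it.

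The deposited log2 values ran from 2.55 to 14.71, and the median of each array lay between 5.33 and 5.50. The 75th percentile of AT2 cytomix with MSCs was 7.09, against 7.42 in AT2 cytomix and 7.49 in AT2 control. Against AT2 cytomix the exact two-sided permutation p was 0.0079, the smallest that these group sizes allow, and 0.0286 after Benjamini-Hochberg adjustment over 18 such tests. The median change over all genes was -0.10 for AT2 cytomix with MSCs against AT2 cytomix and -0.16 against AT2 control. In every AT2 group arrays 2 and 3 were close to each other, with r across genes of 0.998 in control, where the highest other pair reached 0.977. All pairs within MSC control had r of 0.9956 to 0.9961 and within MSC cytomix of 0.9932 to 0.9961, against 0.9238 to 0.9843 in MSC transwell. Whether these close arrays, of AT2 cells or of MSCs, are separate cultures is not given in the sources used here. They may therefore not be separate replicates, and errors and p-values that rest on them may be too small. All p-values measure only the spread between these samples, since the labels do not say whether replicates came from separate donors, and the number of arrays limits the precision. Changes are log2 differences ± SE from limma, and adjusted p-values come from the same fit over 8421 genes. Each gene is given by its brightest probe set. Detection calls were not used here, so a fold against a group whose mean lies at background is a lower bound. The highest value of an array lay between 14.33 and 14.71, and genes near it, such as IL6 and CXCL8 in MSCs given cytomix, have little room to differ further. Where a gene list has no count adjusted over the list alone beside it, that count was the same.

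The question of the first comparison was what cytomix does to alveolar epithelium without MSCs. In AT2 cytomix (n = 4) against AT2 control (n = 5) the largest rise was that of CXCL11, a ligand of the T cell receptor CXCR3, which was 314-fold higher (8.29 ± 1.06). Its relatives CXCL10 and CXCL9 rose 103-fold (6.69 ± 1.10) and 88.4-fold (6.47 ± 1.07). CXCL10 (probe set 204533_at) had a mean of 6.13 ± 2.70 (SD) in control and 12.82 ± 1.61 in cytomix. The water channel gene AQP4 (probe set 210068_s_at) fell 54.8-fold (-5.78 ± 0.83) and SFTPB (209810_at), which encodes surfactant protein B, fell 10.3-fold (-3.37 ± 0.67). Of the 8421 genes, 1275 changed, with 529 higher and 746 lower.

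Interferon-inducible genes rose as a group, with 39 of 49 higher and 0 lower (45 and 0 adjusted over the list alone), a median of 1.69 and a camera adjusted p of 2.0e-27 (adjusted p = 0.172 with an estimated correlation). IDO1, which encodes a tryptophan-degrading enzyme, rose by 6.66 ± 0.84, RSAD2 rose by 4.26 ± 0.50 and IFIT2 by 3.83 ± 0.40. Antigen processing and presentation genes had 11 of 27 higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 0.79 (adjusted p = 1.7e-07, and 0.340 with an estimated correlation). TAP1, a subunit of the peptide transporter, rose 8.53-fold (3.09 ± 0.47). Chemokine genes had 16 of 21 higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 2.26 (adjusted p = 2.0e-13, and 0.153 with an estimated correlation). CCL8 rose 256-fold (SE 0.80) and CXCL8, the neutrophil attractant interleukin 8, rose 4-fold (SE 0.21). For cytokine genes 10 of 25 were higher and 0 lower (14 and 0 adjusted over the list alone), with adjusted p = 4.8e-09, and 0.153 with an estimated correlation. IL1B rose 38.6-fold (5.27 ± 0.94), IL23A 27.5-fold (4.78 ± 0.43, and 2.42 as the mean over 2 probe sets) and IL6 22.1-fold (4.46 ± 0.73).

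Targets and feedback regulators of NF-kappaB had 16 of 26 genes higher and 0 lower (19 and 0 adjusted over the list alone), with adjusted p = 8.0e-13, and 0.153 with an estimated correlation. The inhibitor TNFAIP3 rose 8.09-fold (3.02 ± 0.44). Among genes of oxidative stress and nitric oxide, NOS2, the inducible nitric oxide synthase, rose 7.39-fold (2.89 ± 0.36), DUOX2 rose 16.1-fold (SE 0.66), and CAT, which encodes catalase, fell (-2.62). That list had 11 of 32 higher and 3 lower (12 and 4 adjusted over the list alone), and its adjusted p of 0.0497 became 0.0982 after quantile normalisation, 0.174 with the replicate number as a block and 0.377 with an estimated correlation. Glycolysis and hypoxia genes had 14 of 35 higher and 1 lower (19 and 1 adjusted over the list alone), with adjusted p = 1.9e-08, and 0.179 with an estimated correlation. ADM, a hypoxia-inducible peptide hormone gene, rose by 2.87 ± 0.55. Complement, acute phase and antimicrobial genes had 5 of 28 higher (6 adjusted over the list alone), with adjusted p = 0.0341, which was 0.0637 after quantile normalisation, 0.209 with the block and 0.438 with an estimated correlation.

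Alveolar type II and surfactant genes fell, with 12 of 24 lower and 0 higher (13 and 0 adjusted over the list alone), a median of -1.06 and adjusted p = 4.8e-06, against 0.172 with an estimated correlation. SFTPD, a collectin of the surfactant, fell 9.87-fold (-3.30 ± 0.75) and LPCAT1, an enzyme of surfactant lipid synthesis, fell by 2.74 ± 0.43. SFTPC, the gene of surfactant protein C, had -0.99 ± 0.77 and was not past the test (adjusted p = 0.411). Alveolar type I genes had 12 of 21 lower and 0 higher (15 and 1 adjusted over the list alone), a median of -1.60 and adjusted p = 7.3e-07, against 0.179 with an estimated correlation. The fall was not particular to alveolar genes, as epithelial markers (camera adjusted p = 0.00854) and cell cycle genes (0.00275) fell too. Neither of these was past the test with an estimated correlation. Without AT2 cytomix 1 their medians were -0.88 and -0.55. Genes of ion and fluid transport had 9 of 27 lower and 2 higher (11 and 4 adjusted over the list alone), and were not past the test (adjusted p = 0.0277 after quantile normalisation and 0.0346 with the block). CFTR, a chloride channel gene, fell 5.52-fold (-2.46 ± 0.57), and SCNN1A, a subunit of the epithelial sodium channel, fell by 1.57 ± 0.38. Junction genes had 2 higher and 2 lower of 21 in either count (adjusted p = 0.929). CLDN18 fell by 3.15 ± 0.88 whereas CLDN4 rose by 0.96 ± 0.18. PTGS2, the inducible cyclooxygenase gene, had 0.93 ± 0.31 (adjusted p = 0.0586, and 0.00921 with the block).

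AT2 cytomix array 1 stood apart from its group, with a mean of 8.05 over the interferon-inducible genes (9.28 to 9.40 in the other cytomix arrays). AT2 control 4 had 8.29 there and the other controls 6.66 to 6.95. Over the alveolar type I genes its mean was 8.72 (6.98 to 7.20 in the other cytomix arrays). Across genes cytomix 1 had r of 0.9839 with control 5 and 0.9808 with control 1, against 0.9498 to 0.9621 with the other cytomix arrays. The count of changed genes was 1913 without that array, and it was 765 without control 2, 785 without control 3, 489 without cytomix 2, 494 without cytomix 3 and 715 without cytomix 4. With arrays 2 and 3 averaged in each group, a setting chosen after these values were seen, 60 genes changed, 20 of the 85 named genes past the test stayed past it, among them CXCL11, CCL8, IDO1 and AQP4, and CXCL10 (0.0674) and SFTPB (0.0979) did not.

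**Figure D1:**
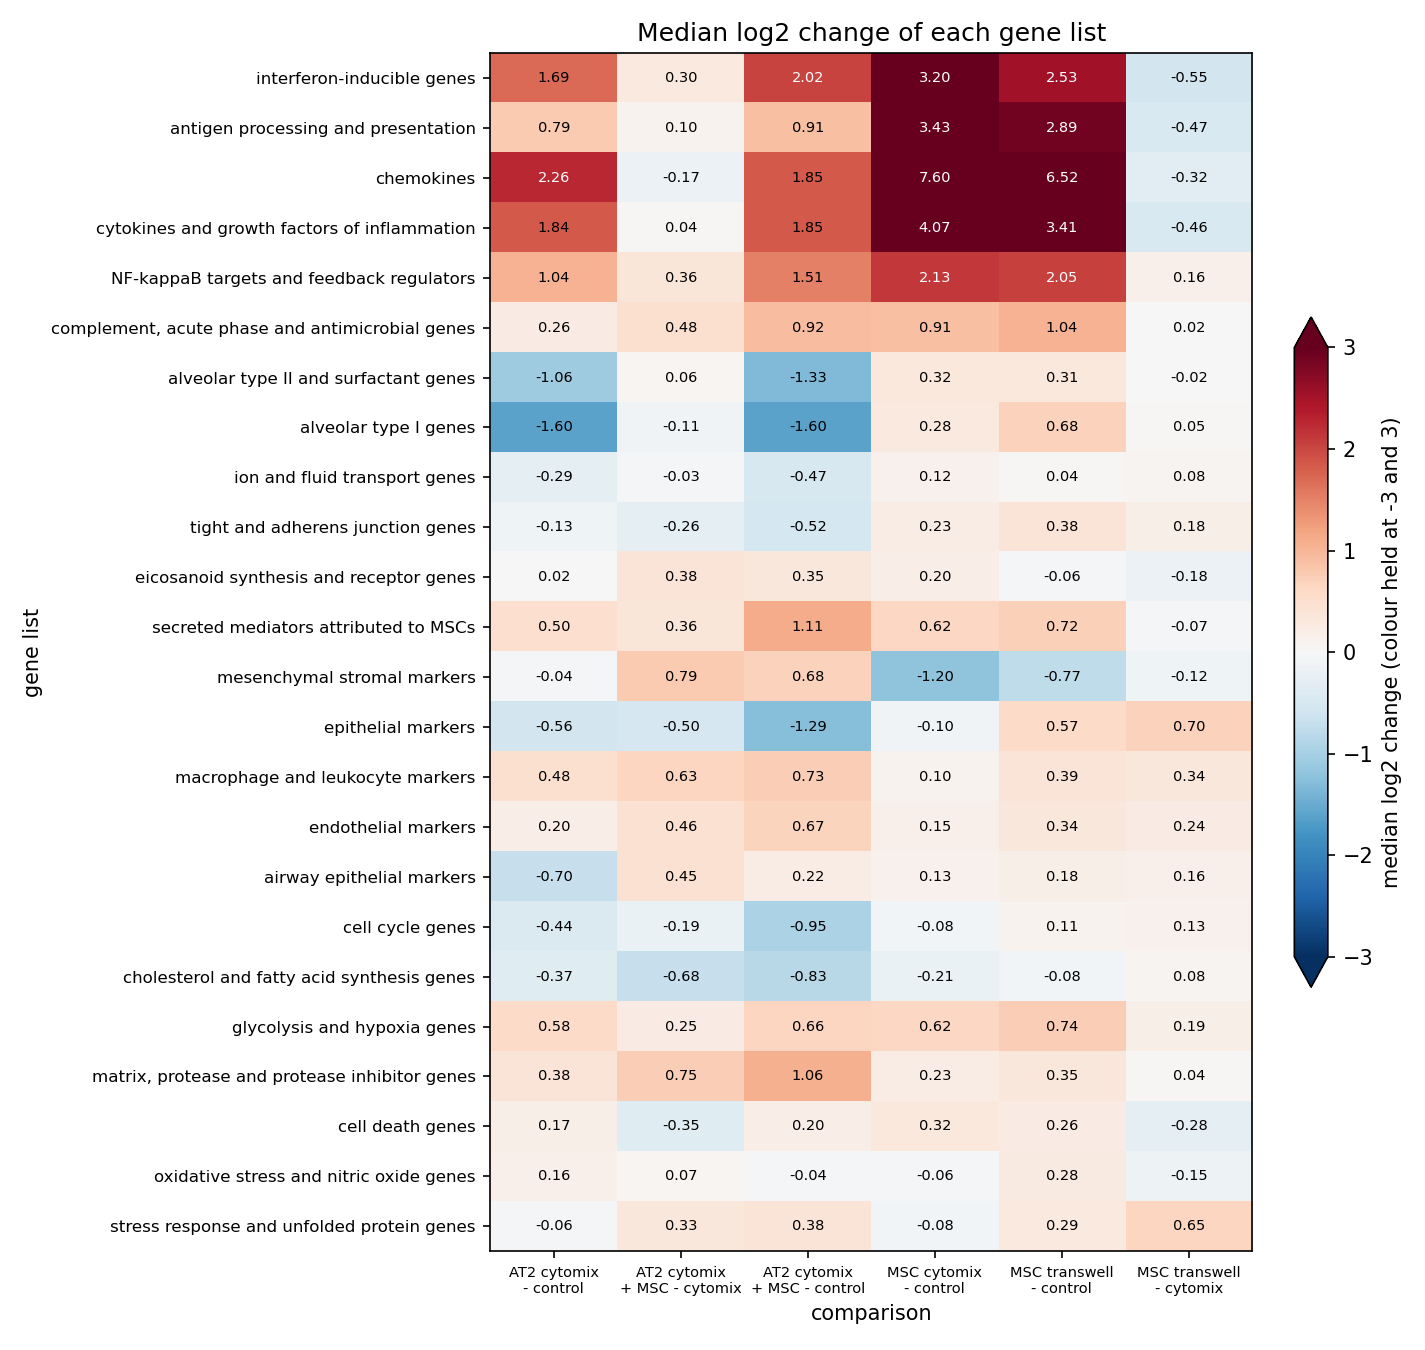
Median log2 change of each of the 24 gene lists (vertical axis) in each of the 6 comparisons within a cell type (horizontal axis), with colour held at -3 and 3. Chemokine genes had medians of 2.26 in AT2 cells and 7.60 in MSCs given cytomix; after quantile normalisation the sign changed only for medians between -0.08 and 0.

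Co-culture was examined to learn which genes of injured AT2 cells differed when MSCs shared the medium. In AT2 cytomix with MSCs (n = 5) against AT2 cytomix (n = 4), GADD45B (probe set 207574_s_at), a stress-induced regulator of growth arrest, rose 7.86-fold (2.97 ± 0.29), from a mean of 7.34 ± 0.76 (SD) to 10.31 ± 0.25. TUBA1A (209118_s_at), which encodes an alpha tubulin, fell 13.5-fold (-3.75 ± 0.26) and SFPQ, a splicing factor gene, fell 11.6-fold (-3.53 ± 0.23). SFTPB rose 3.77-fold (1.91 ± 0.67), part of the way back to its control level. CXCL10 (0.91 ± 1.10, adjusted p = 0.515), IL6 (0.72, adjusted p = 0.435) and IDO1 (-0.82 ± 0.84, adjusted p = 0.434) were not past the test, the mean of CXCL10 with MSCs being 13.73. In all, 4363 genes changed, 1717 higher and 2646 lower, and after quantile normalisation 4126 changed, 2127 higher and 1999 lower.

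Stress response and unfolded protein genes rose, with 13 of 37 higher and 3 lower (the same adjusted over the list alone), a median of 0.33 and adjusted p = 0.0154, against 0.00775 after quantile normalisation, and without array 5 of the group with MSCs the median was 0.21. DDIT3, a transcription factor gene of the unfolded protein response, rose 6.64-fold (2.73 ± 0.25), and RSRP1 rose 8.23-fold (3.04 ± 0.21). Interferon-inducible genes had 12 of 49 higher and 4 lower (11 and 3 adjusted over the list alone), with a median of 0.30 and adjusted p = 0.0250, which was 0.0755 after quantile normalisation. Without AT2 cytomix 1 that list had a median of 0.058, with 10 higher and 6 lower, and adjusted p = 0.389. OASL rose by 2.29 ± 0.30. Glycolysis and hypoxia genes had 11 of 35 higher and 5 lower in either count, with adjusted p = 0.0250, which was 0.0755 after quantile normalisation and 0.122 without AT2 cytomix 1. ANGPTL4, a secreted regulator of lipid metabolism, rose by 2.72 ± 0.34. With an estimated correlation none of the lists of this comparison was past the test, the lowest adjusted p being 0.855.

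Mesenchymal stromal markers had 10 of 31 higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 0.79 and adjusted p = 0.0154, which was 0.0715 after quantile normalisation. With an estimated correlation this list and those of matrix, secreted mediator, complement and endothelial genes each had an adjusted p of 0.855. POSTN (probe set 210809_s_at), a matrix protein gene, rose 14.9-fold (3.89 ± 1.15), SERPINE2 15.5-fold (3.96 ± 0.99) and LOX, a collagen cross-linking enzyme gene, 7.27-fold (2.86 ± 0.77). Matrix, protease and protease inhibitor genes had 10 of 37 higher and 4 lower (9 and 3 adjusted over the list alone), with adjusted p = 0.0250 (0.0611 without AT2 cytomix 1), and MMP10, a stromelysin gene, rose 17.8-fold (4.15 ± 0.77). Secreted mediators attributed to MSCs had 7 of 29 higher and 0 lower (3 and 0 adjusted over the list alone), with adjusted p = 0.0250 (0.110 without AT2 cytomix 1). Like the matrix list, it had an adjusted p of 0.118 after quantile normalisation. Complement, acute phase and antimicrobial genes had 7 of 28 higher and 1 lower (4 and 1 adjusted over the list alone), with adjusted p = 0.0250, which was 0.118 after quantile normalisation and 0.110 without AT2 cytomix 1, and PTX3, a soluble pattern recognition gene, rose by 2.29 ± 0.53. Endothelial markers had 4 of 7 higher (adjusted p = 0.0250, 0.107 after quantile normalisation and 0.0856 without AT2 cytomix 1). In array 5 of this group 9 genes bright in MSCs and dim in AT2 cells stood at levels that MSC RNA would give at a median share of 16.6%, against 0.03% to 2.62% in arrays 1 to 4. Without array 5, POSTN had 3.03 (adjusted p = 0.0244), SPARC had 2.21 (adjusted p = 0.0569), and the list of secreted mediators was not past the test (adjusted p = 0.0531). The mesenchymal list then had a median of 0.42, with 7 of 30 higher, and adjusted p = 0.0467.

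TJP1, which encodes a scaffold of tight junctions, fell 2.94-fold (-1.56 ± 0.25) and CDH1, the E-cadherin gene, fell 1.82-fold (-0.86 ± 0.14). Junction genes as a list had 7 of 21 lower and 0 higher in either count and were not past the test (adjusted p = 0.375). Epithelial markers had 10 of 24 lower and 3 higher in either count and were not past it either (adjusted p = 0.298), and KRT19 fell by 2.62 ± 0.38. Cholesterol and fatty acid synthesis genes had 14 of 29 lower and 3 higher (15 and 3 adjusted over the list alone), with a median of -0.68 and adjusted p = 0.123, and a median of -0.36 with 11 lower without AT2 cytomix 1. Cell death genes had 11 of 29 lower and 4 higher in either count (adjusted p = 0.501), and the adaptor FADD (-2.32 ± 0.27) and CASP8 (-1.63 ± 0.15), which pass on death receptor signals, fell. NOS2 fell 2.36-fold (-1.24 ± 0.36), and SLC7A11, a cystine transporter gene, fell by 2.86 ± 0.55.

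Chemokine genes had 1 of 21 higher and 3 lower (0 and 3 adjusted over the list alone), with a median of -0.17 and an adjusted p of 0.937 for a test whose direction was up. Without AT2 cytomix 1 the direction was down, with 0 higher, 5 lower, a median of -0.745 and adjusted p = 0.383. CXCL2 fell by 1.95 ± 0.32 and CXCL3 by 2.21 ± 0.53. With the block, antigen processing and presentation genes (1 of 27 higher and 1 lower, 1 and 0 adjusted over the list alone, adjusted p = 0.298) had 0.0377. Macrophage and leukocyte markers (1 of 24 higher, adjusted p = 0.144) had 0.000596 and airway epithelial markers (4 of 10 higher, 1 adjusted over the list alone, adjusted p = 0.0928) had 0.0302. Alveolar type II and surfactant genes had 5 of 24 higher and 6 lower in either count (adjusted p = 0.501). LPCAT1 fell (-1.92), SFTPC had 1.63 ± 0.77 (adjusted p = 0.0894) and SFTPD had 1.03 ± 0.75 (adjusted p = 0.270, and 0.0277 with the block). Without AT2 cytomix 1, SFTPB had 2.74 (adjusted p = 0.000822) and SFTPC 2.17 (adjusted p = 0.0360). Of the named genes past the test, 77 stayed so with arrays 2 and 3 averaged, POSTN, SPARC, SFTPB and NOS2 not among them.

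**Figure D2:**
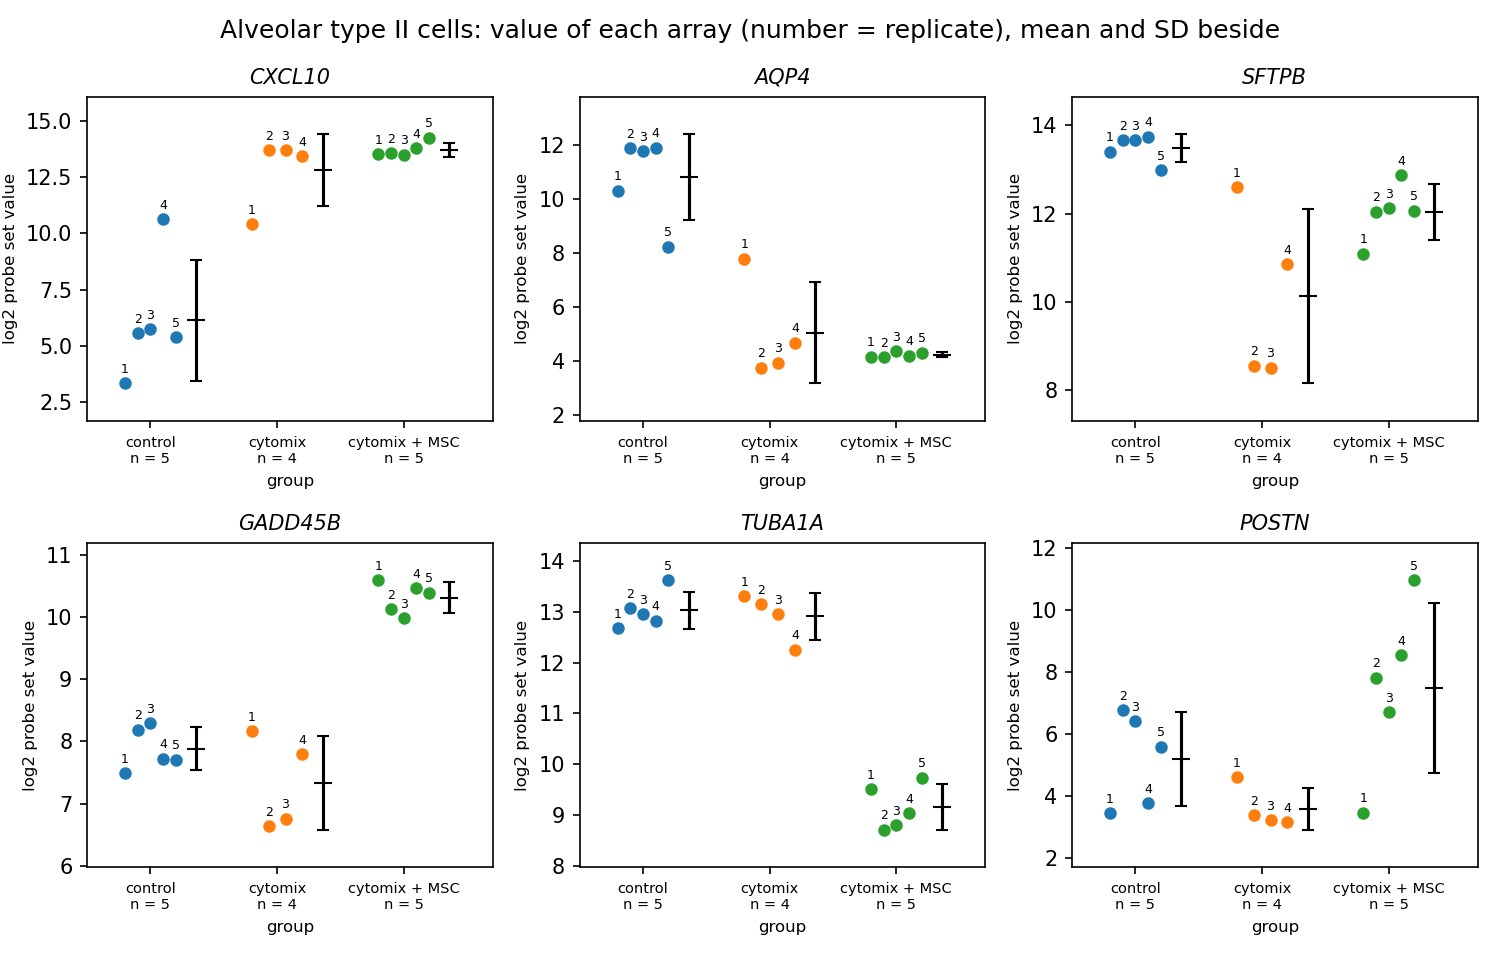
Log2 probe set value (vertical axis) of 6 genes in each AT2 array, numbered by replicate, in the control, cytomix and cytomix with MSC groups (n = 5, 4 and 5), with the mean and SD beside the points. TUBA1A had a mean of 12.91 in cytomix and 9.16 with MSCs, and POSTN was highest in array 5 of the group with MSCs.

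Whether the combined treatment left AT2 cells closer to the unstimulated state was asked by comparing AT2 cytomix with MSCs (n = 5) with AT2 control (n = 5). CXCL11 was 279-fold higher (8.12), CXCL10 194-fold (7.60 ± 1.04) and CCL5, a T cell attractant, 163-fold (7.35 ± 0.94). AQP4 was 96.1-fold lower (-6.59 ± 0.78), its mean of 4.23 being near the lowest values, and ID1, an inhibitor of differentiation factors, 46-fold lower (-5.52 ± 0.70). A total of 5814 genes changed, 2425 higher and 3389 lower, and after quantile normalisation 5588 changed, 2907 higher and 2681 lower. Interferon-inducible genes had 42 of 49 higher and 0 lower (43 and 0 adjusted over the list alone), with adjusted p = 5.1e-13. No list of this comparison stayed past the test with an estimated correlation, the lowest adjusted p being 0.371.

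Alveolar type I genes had 16 of 21 lower and 1 higher (17 and 1 adjusted over the list alone), with adjusted p = 0.00646, against 0.513 with an estimated correlation. Epithelial markers (camera adjusted p = 0.0312), cell cycle genes (0.0485) and cholesterol and fatty acid synthesis genes (0.0120) fell too. Without array 5 of the group with MSCs their medians were -1.28, -0.98 and -0.765. For alveolar type II and surfactant genes 13 of 24 were lower and 3 higher, with adjusted p = 0.106 (0.0411 after quantile normalisation). NKX2-1, the transcription factor gene of lung epithelium, fell by 2.80 ± 0.27 and LPCAT1 by 4.66 ± 0.41, whereas SFTPB had -1.46 ± 0.63 (adjusted p = 0.0542, and 0.0121 with the mean over probe sets). CFTR was still lower (-2.40, adjusted p = 0.00139), as was SFTPD (-2.27, adjusted p = 0.0113), the latter not past the test with arrays 2 and 3 averaged. Mesenchymal stromal markers had 12 of 31 higher and 2 lower (10 and 1 adjusted over the list alone), with adjusted p = 0.0295, which was 0.0978 after quantile normalisation and 0.127 without array 5, where those 9 genes were high, and 0.580 with an estimated correlation. ATF3, an early stress gene, rose 20.1-fold (4.33 ± 0.28). Macrophage and leukocyte markers had 2 of 24 higher and 1 lower (1 and 1 adjusted over the list alone), and were not past the test (adjusted p = 0.0719). They were past it with the block (0.000702), without array 5 (0.0326) and with arrays 2 and 3 averaged (0.044). Airway epithelial markers had 4 of 10 higher and 1 lower, with a median of 0.22, a mean of -0.23 and an adjusted p of 0.340. Endothelial markers had 6 of 7 higher (adjusted p = 0.00715, and 0.371 with an estimated correlation).

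Of the 1275 genes that changed with cytomix alone, 157 changed the opposite way when MSCs were added and 410 changed further the same way. Of those that rose with cytomix 117 changed the opposite way and 102 the same way, and of those that fell 40 and 308 did. Independence of the comparisons would give 318.3 and 342.3 genes, but they share arrays, so these are not the counts expected without an effect of co-culture. In 100 simulated draws without such an effect the median was 0 for both counts. Without an effect hardly any gene can pass the second comparison, so counts near 0 were fixed by the setting. The draws therefore do not show whether 157 or 410 is many among genes that respond to co-culture. KYNU, which encodes kynureninase, rose by 3.35 with cytomix and fell by 2.81 with MSCs, and its level with MSCs was 0.54 from control. TGFBI, a matrix protein gene, fell by 2.49 with cytomix and rose by 2.80 with MSCs. AIM2, a DNA sensor of the inflammasome, rose by 3.28 and fell by 2.38. The count of opposite changes was 324 without AT2 cytomix 1, 86 without control 2, 93 without control 3, 51 without cytomix 2, 54 without cytomix 3, 74 without cytomix 4, 282 with the block and 9 with arrays 2 and 3 averaged. Both comparisons use the AT2 cytomix arrays. With different cytomix arrays for each, the 6 possible divisions gave 7, 7, 5, 66, 54 and 57 opposite genes and 6, 6, 5, 517, 317 and 313 that changed the same way, of 35, 35, 23, 1446, 1081 and 1093 changed with cytomix. Only the divisions with 5 and 66 opposite genes kept cytomix arrays 2 and 3 (r of 0.998) on the same side. In the others the sides may not be separate.

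What cytomix does to MSCs alone was measured in MSC cytomix (n = 3) against MSC control (n = 3). MMP3, a stromelysin gene, rose 995-fold (9.96 ± 0.32), and MMP12 (probe set 204580_at), the macrophage elastase gene, rose 905-fold (9.82 ± 0.38), from a mean of 3.54 ± 0.07 (SD), near the lowest values measured, to 13.37 ± 0.04. CXCL9 rose 882-fold (9.78 ± 0.27) and CXCL10 855-fold (9.74 ± 0.39). COL1A1 (202310_s_at), which encodes the main chain of type I collagen, fell 31.6-fold (-4.98 ± 0.43) and ACTA2, the smooth muscle actin gene, fell 50.1-fold (-5.65 ± 0.29). A total of 2246 genes changed, 945 higher and 1301 lower, and this count ranged from 1650 to 1724 without any 1 of the arrays of these groups. It was 4990 in a fit on these arrays alone and 5154 with array weights. The errors and p-values of this comparison come from the fit on all 11 MSC arrays. They therefore hold the spread of MSC transwell too, not that of the groups compared alone.

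Interferon-inducible genes had 45 of 49 higher and 0 lower (48 and 0 adjusted over the list alone), a median of 3.20 and adjusted p = 6.0e-37. Antigen processing and presentation genes had 25 of 27 higher and 0 lower, with adjusted p = 3.7e-30, and HLA-DRA, a class II gene, rose 457-fold (8.84 ± 0.33). Chemokine genes had 17 of 21 higher and 1 lower, with a median of 7.60 and adjusted p = 3.1e-17. CXCL8 rose 118-fold (6.88 ± 0.11). Cytokine genes had 21 of 23 higher and 0 lower (adjusted p = 3.0e-19), and IL6 rose 32.7-fold (5.03 ± 0.09). NF-kappaB targets had 21 of 26 higher and 1 lower (22 and 1 adjusted over the list alone), with adjusted p = 2.6e-15. Secreted mediators attributed to MSCs had 14 of 34 higher and 5 lower (adjusted p = 1.5e-06). These 6 lists held with an estimated correlation, at adjusted p-values from 0.00015 to 0.00636.

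Several of those mediators are proposed carriers of the paracrine effects of MSCs. IL1RN, the gene of the interleukin 1 receptor antagonist, rose 43.7-fold (5.45 ± 0.25, and 1.64 as the mean over its 5 probe sets), TNFAIP6, which encodes the anti-inflammatory protein TSG-6, 16.1-fold (4.01 ± 0.24) and IDO1 450-fold (8.81 ± 0.37). PTGS2 (probe set 204748_at) rose 262-fold (8.03 ± 0.23) and PTGES, the prostaglandin E synthase gene, 17.1-fold (4.10 ± 0.15), while PTGIS, the prostacyclin synthase gene, fell 18.9-fold (-4.24 ± 0.40, and -2.003 as the mean over 3 probe sets). ANGPT1 (0.18, adjusted p = 0.659), FGF7 (0.53, adjusted p = 0.538) and HGF (0.30, adjusted p = 0.244), growth factor genes, were not past the test, though HGF was with the mean over its probe sets (0.72, adjusted p = 0.0229). Eicosanoid genes had 6 of 24 higher and 3 lower (7 and 3 adjusted over the list alone), with adjusted p = 0.0662.

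Mesenchymal stromal markers had 19 of 33 lower and 4 higher (22 and 5 adjusted over the list alone), a median of -1.20 and adjusted p = 2.2e-05, against 0.142 with an estimated correlation. Matrix, protease and protease inhibitor genes had 13 of 37 higher and 7 lower (15 and 8 adjusted over the list alone), with adjusted p = 0.00694 (0.0265 with an estimated correlation), and MMP1, the interstitial collagenase gene, rose 626-fold (9.29 ± 0.17). Cell cycle genes had 2 of 18 lower and 0 higher (adjusted p = 0.402). Oxidative stress and nitric oxide genes had 10 of 30 higher and 6 lower (11 and 8 adjusted over the list alone), with a median of -0.06, a mean of 0.72 and adjusted p = 0.0247, against 0.249 with an estimated correlation. GCH1, which encodes the cofactor-making enzyme for nitric oxide synthases, rose 277-fold (8.12 ± 0.41).

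MSCs from co-culture were set against MSC control to describe their state beside injured epithelium. In MSC transwell (n = 5) against MSC control (n = 3), MMP1 rose by 10.40 ± 0.15, from a mean of 3.30 ± 0.27 (SD) to 13.70 ± 0.13. CCL5 rose 968-fold (9.92 ± 0.20), CXCL10 816-fold (9.67 ± 0.35) and PTGS2 257-fold (SE 0.21). COL1A1 fell 82.3-fold (-6.36 ± 0.38) and CXCL12, a chemokine gene of stromal niches, fell 36.5-fold (-5.19 ± 0.25). In this comparison 4111 genes changed, 1700 higher and 2411 lower. IL1RN rose 100-fold (6.65 ± 0.22, and 2.27 as the mean over its probe sets), while ANGPT1 fell (-1.13 ± 0.21, adjusted p = 0.000832) and FGF7 fell (-1.43 ± 0.48, adjusted p = 0.0281).

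Interferon-inducible genes had 44 of 49 higher and 0 lower in MSC transwell, with adjusted p = 1.5e-22, and chemokine genes had 17 of 21 higher and 1 lower (19 and 1 adjusted over the list alone), with adjusted p = 9.7e-12. They held with an estimated correlation (adjusted p = 0.00104 and 0.000677), as did the antigen, cytokine, NF-kappaB, complement, secreted mediator and matrix lists. Glycolysis and hypoxia genes had 24 of 36 higher and 3 lower (25 and 4 adjusted over the list alone), with adjusted p = 5.7e-07, against 0.101 with an estimated correlation. Mesenchymal stromal markers had 17 of 33 lower and 5 higher (18 and 5 adjusted over the list alone), with adjusted p = 0.0125, against 0.441 with an estimated correlation. ASNS, the asparagine synthetase gene, fell by 5.09 and ATF3 rose by 5.60. Cell cycle genes had 1 of 18 higher and 6 lower, with a median of 0.11, a mean of -0.36 and adjusted p = 0.936.

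**Figure D3:**
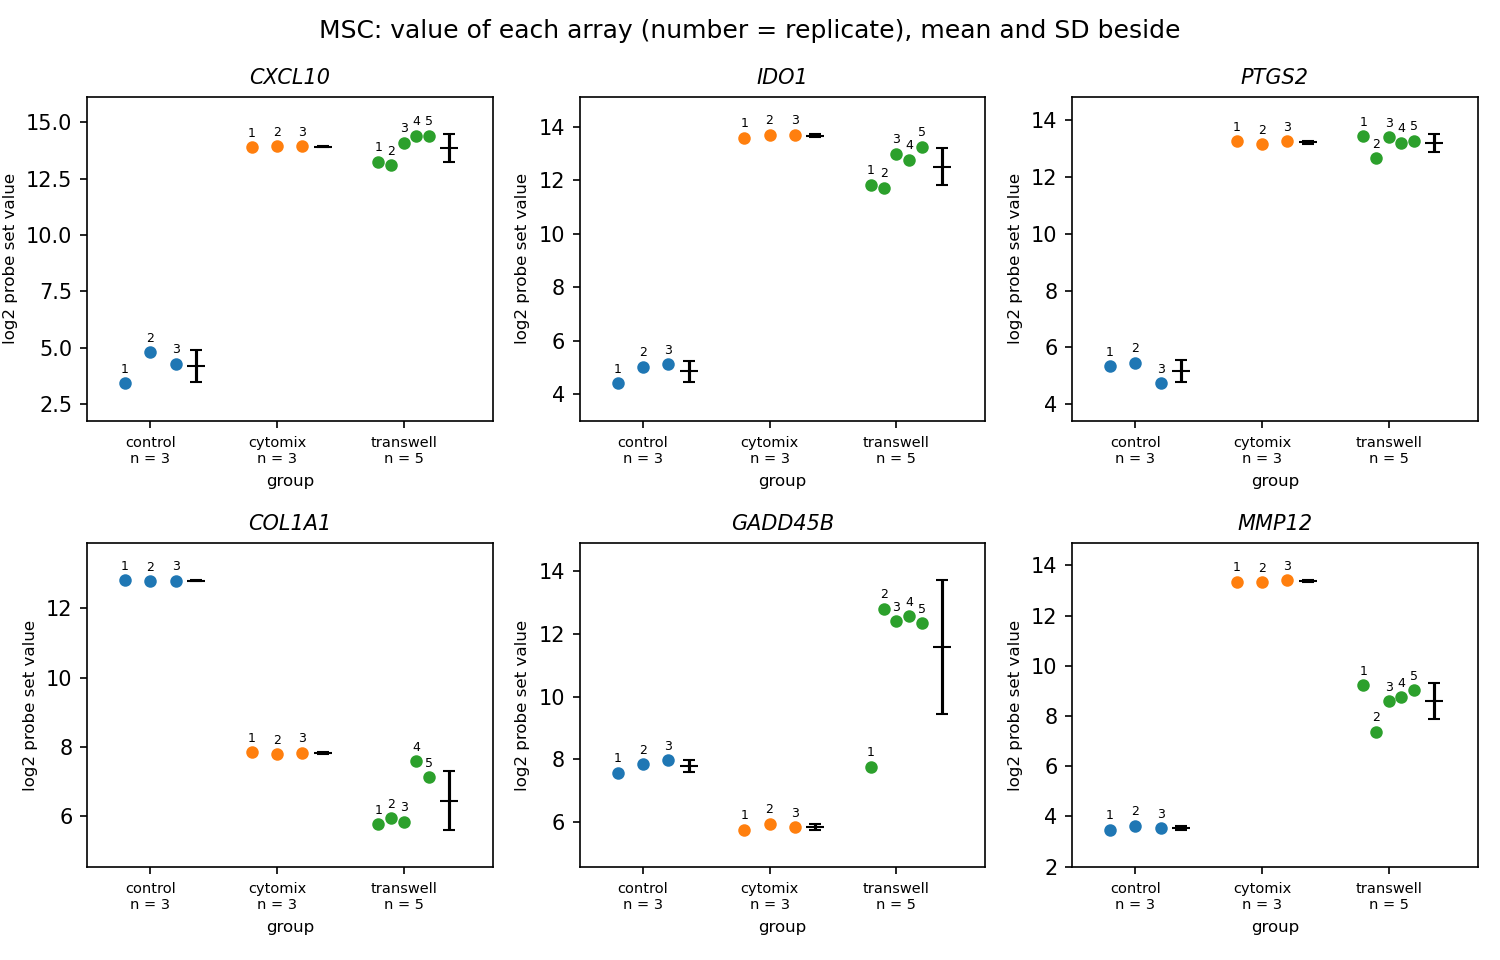
Log2 probe set value (vertical axis) of 6 genes in each MSC array, numbered by replicate, in the control, cytomix and transwell groups (n = 3, 3 and 5), with the mean and SD beside the points. MMP12 had means of 3.54, 13.37 and 8.59, and GADD45B of 7.79, 5.85 and 11.57 with an SD of 2.14 in the transwell group.

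The difference made by AT2 cells was sought in MSC transwell (n = 5) against MSC cytomix (n = 3), both exposed to cytomix if the protocol applies to the former. GADD45B rose 53-fold (5.73 ± 0.91), HES1, a Notch target gene, 43.4-fold (5.44 ± 0.84) and SOCS2, a feedback inhibitor of cytokine signalling, 20-fold (4.32 ± 0.57). MMP12 fell 27.3-fold (-4.77 ± 0.34) and ASNS 27.1-fold (-4.76 ± 0.25). CXCL10 (-0.07, adjusted p = 0.907), IL6 (-0.01, adjusted p = 0.926) and PTGS2 (-0.03, adjusted p = 0.931) were not past the test. IL6 had means of 14.54 and 14.53, at the highest values of the arrays, so that a difference could not have shown. The count was 2659, with 1115 higher and 1544 lower, and it was 1680 without MSC cytomix 2 and 1701 without MSC cytomix 3.

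Interferon-inducible genes had 16 of 49 lower and 5 higher (18 and 5 adjusted over the list alone), with a median of -0.55 and adjusted p = 0.0299, against 0.516 with an estimated correlation. IDO1 fell (-1.15 ± 0.33, adjusted p = 0.0198). Antigen processing and presentation genes had 10 of 27 lower and 1 higher (16 and 1 adjusted over the list alone), with adjusted p = 0.00440, against 0.516 with an estimated correlation. Chemokine genes had 6 of 21 lower and 0 higher in either count (adjusted p = 0.0871, and 0.0497 after quantile normalisation), and CXCL1 fell by 3.38. Stress response genes had 17 of 37 higher and 6 lower (19 and 7 adjusted over the list alone), with a median of 0.65 and adjusted p = 0.0346, against 0.516 with an estimated correlation. ZFP36, which encodes an RNA-destabilising protein, rose by 3.94 ± 0.60. Epithelial markers had 6 of 12 higher and 0 lower in either count (adjusted p = 0.0299, and 0.516 with an estimated correlation). In these arrays 3 to 8 of 13 genes bright in AT2 cells and dim in MSCs lay above every MSC array without AT2 cells, at median AT2 shares of -0.13% to 1.29%. Of the glycolysis genes 11 of 36 were higher and 3 lower (adjusted p = 0.0299, and 0.516 with an estimated correlation). IL1RN rose (1.20 ± 0.22, and 0.63 as the mean over its probe sets), NOS2 fell (-1.84 ± 0.15, adjusted p = 5.6e-06), and ANGPT1 (-1.31 ± 0.21) and FGF7 (-1.96 ± 0.48) fell. Secreted mediators had 8 of 34 higher and 9 lower (8 and 13 adjusted over the list alone), with adjusted p = 0.724.

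Co-culture differences in AT2 cells and in MSCs share no array, so they could be set side by side for the 7982 genes tested in both. Across genes, which are not independent replicates, Pearson's r was 0.555 and Spearman's rho 0.548. Both cell types showed a rise for 396 genes, against 225.9 under independence (Fisher's exact p = 2.3e-38), and a fall for 1039, against 472.5 (p = 2.6e-251). Opposite changes were seen in 123 genes, against 653.9. GADD45B, ZFP36 and ANGPTL4 rose in both cell types, by 2.97, 1.45 and 2.72 in AT2 cells and by 5.73, 3.94 and 2.61 in MSCs. TJP1, SLC7A11 and PCNA fell in both, by 1.56, 2.86 and 1.80 in AT2 cells and by 1.66, 3.73 and 1.99 in MSCs (adjusted p = 0.0864 for TJP1 in MSCs with the mean over probe sets). In MSC transwell 1 GADD45B stood at 7.76, against 12.35 to 12.81 in the other arrays of that group.

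**Figure D4:**
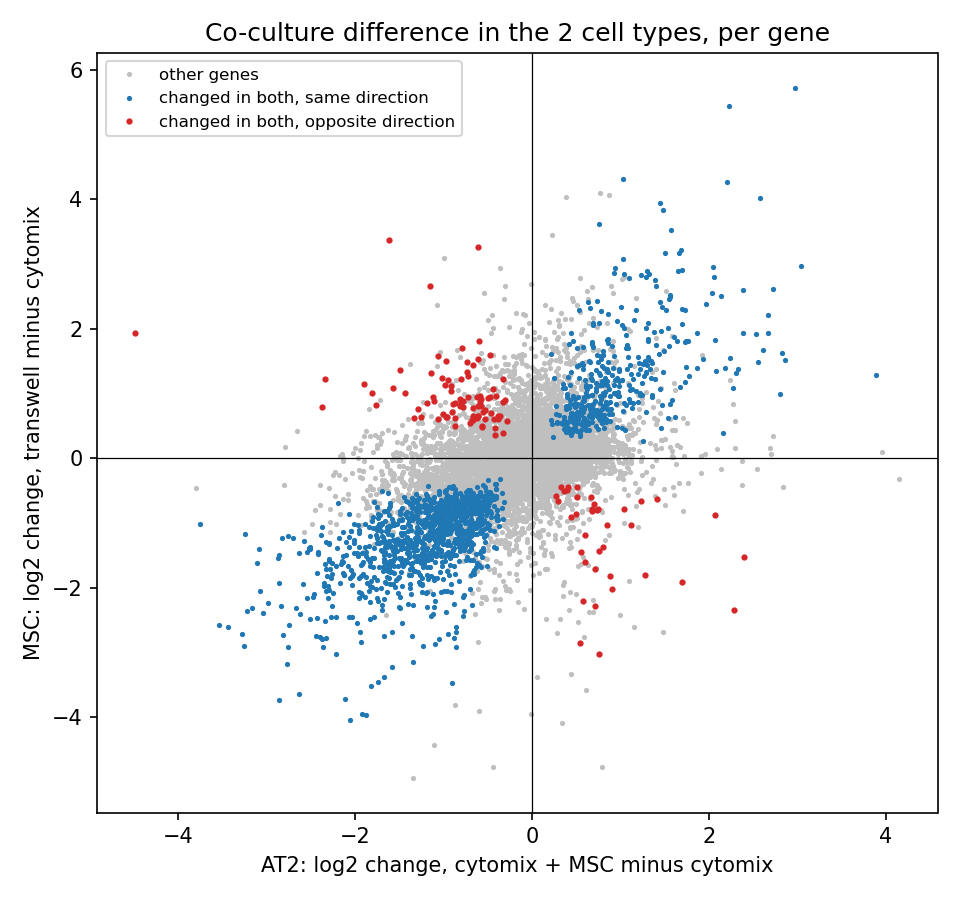
Each point is a gene, with its log2 co-culture difference in AT2 cells on the horizontal axis (cytomix with MSCs minus cytomix) and in MSCs on the vertical axis (transwell minus cytomix). Genes past the test in both are blue where the directions were the same (396 higher, 1039 lower) and red where they were opposite (123).

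To learn whether the cell types answer cytomix differently, the AT2 response was tested against the MSC response over all 25 arrays. The response of SLC39A8, a zinc transporter gene, was lower in AT2 cells by 9.09 ± 0.55, since it rose in MSCs from 4.51 to 12.04 and went from 12.17 to 10.61 in AT2 cells. PTGS2 differed by -7.10 ± 0.43, its AT2 control mean being 11.33 ± 0.53 (SD) and its MSC control mean 5.18 ± 0.39. HLA-DRA (-7.65 ± 1.01), MMP1 (-7.51 ± 1.23) and CXCL8 (-4.88 ± 0.27) also rose more in MSCs. CXCL8 ended near the highest values of the arrays in both, at 13.94 in AT2 cells and 14.14 in MSCs, from 11.94 and 7.26, so its difference follows its levels in the controls. RGS4, a regulator of G protein signalling, differed by 6.48 ± 0.78, and MEST by 6.19 ± 0.43. CXCL10 (-3.05, adjusted p = 0.172), IL6 (-0.57, adjusted p = 0.768) and NOS2 (0.45, adjusted p = 0.612) were not past the test.

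Responses differed for 1094 genes, 534 higher in AT2 cells and 560 lower. As many were given by 8 of 100 splits of the arrays, the real one included, each with the MSC groups whole or exchanged. Interferon-inducible genes had 17 of 49 lower in AT2 cells and 0 higher (29 and 0 adjusted over the list alone), with adjusted p = 8.4e-13, against 0.232 with an estimated correlation. Antigen processing and presentation genes had 20 of 27 lower and 0 higher (23 and 0 adjusted over the list alone), with adjusted p = 3.3e-20, against 0.0907 with an estimated correlation. Alveolar type II and surfactant genes had 12 of 23 lower (adjusted p = 8.2e-07, and 0.0907 with an estimated correlation), SFTPB among them (-3.74 ± 0.92). Mesenchymal stromal markers had 7 of 33 higher and 2 lower (10 and 2 adjusted over the list alone), with adjusted p = 0.00278, against 0.530 with an estimated correlation. Across the 7982 genes tested in both cell types the responses had r of 0.574 and rho of 0.471. A rise in both was found for 289 genes, against 56.9 under independence (Fisher's exact p = 1.4e-154), and a fall for 250, against 99 (p = 2.0e-52).

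AT2 control (n = 5) and MSC control (n = 3) were compared to place the markers of each cell type. HOPX was 636-fold higher in AT2 cells (9.31 ± 0.74), SFTPB 410-fold (8.68 ± 0.64) and CDH1 270-fold (8.08 ± 0.19). PTX3 was 318-fold lower in AT2 cells (-8.31 ± 0.55), CXCL12 313-fold (-8.29 ± 0.36) and POSTN 257-fold (SE 0.99). In all, 3183 genes differed, 1609 higher and 1574 lower in AT2 cells. Epithelial markers had 20 of 22 higher and 1 lower (21 and 1 adjusted over the list alone; adjusted p = 1.5e-21, and 0.00254 with an estimated correlation) and junction genes 18 of 21 higher (adjusted p = 6.3e-16, and 0.00141 with an estimated correlation). Cholesterol and fatty acid synthesis genes had 20 of 29 higher (21 adjusted over the list alone; adjusted p = 2.7e-09, and 0.0183 with an estimated correlation). Mesenchymal stromal markers had 29 of 33 lower and 1 higher (adjusted p = 1.3e-15, and 0.0511 with an estimated correlation). Macrophage and leukocyte markers had 9 of 21 higher (adjusted p = 0.00528, and 0.445 with an estimated correlation), LYZ among them (5.24 ± 1.41). HGF (-0.19, adjusted p = 0.313) was not past the test, and ANGPT1 (-2.70) and FGF7 (-3.65) were lower in AT2 cells.

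**Figure D5:**
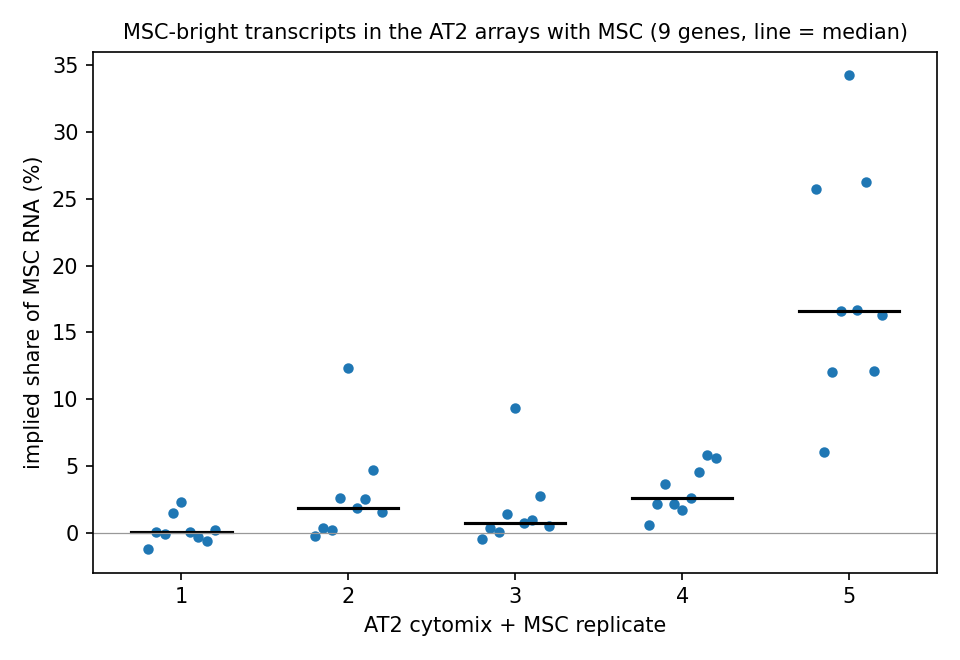
Share of MSC RNA (vertical axis, in %) that would give the level of each of 9 genes bright in MSC transwell and dim in AT2 cells, for each AT2 cytomix with MSC array (horizontal axis, replicate number), with the median as a line. The median was 16.6% in array 5 and between 0.03% and 2.62% in arrays 1 to 4.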

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

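Counts over other splits of the arrays, the score of co-culture across cell types and the comparison of genes within and outside the mesenchymal lists were fixed before their results were seen, and the other tests of explanations were chosen only after. Within groups of 4 or 5 arrays, an array was singled out when its gap to the nearest other array took most of the range of its group (Dixon's test). Chance singles out about 1 in 20 groups if the arrays are independent. Among 96 list means, 12 were singled out, with 4.8 expected on that basis. Among 112 values of fixed genes 13 were, with 5.6 expected, and among 12 measures of array quality 0, with 0.6 expected. Every AT2 group held arrays close to each other, which may not be separate replicates, so the expected counts may be too low there. List means and genes of the same array are not independent of each other either. The excess over the expected counts therefore does not show that chance is excluded.

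AT2 cytomix 1 held 6 of the 12 list means and 5 of the 13 gene values. Its mean log2 level was the lowest of its group for interferon-inducible genes (8.05, others 9.28 to 9.40), antigen presentation genes (9.80, others 10.52 to 10.53), complement and antimicrobial genes (7.69, others 8.44 to 8.53), endothelial markers (4.39, others 4.61 to 4.66) and cell death genes (7.06, others 7.42 to 7.49). It was the highest for alveolar type I genes (8.72, others 6.98 to 7.20). Single genes followed, with CXCL10 at 10.41 (others 13.45 to 13.72), CXCL9 at 10.08 (others 13.22 to 13.27) and CXCL8 at 13.62 (others 14.03 to 14.08) the lowest. HPGD at 5.00 (others 4.05 to 4.16) and AQP5 at 5.64 (others 4.36 to 4.51) were the highest.

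AT2 cytomix 1 lay closer to the controls (distance 1.46 over 315 genes) than to the other cytomix arrays (2.46). On these genes 0 control arrays lay closer to the cytomix arrays than to the other controls, but the genes were chosen as separating those arrays. Across all genes the controls had r of at least 0.9605 with each other and of at most 0.9454 with cytomix 2 to 4, which argues against a label exchanged with a control. Whether the culture of that number responds less stays open. AT2 cytomix with MSCs 1 showed 98.8% of the fall of its group for fallen genes (middle 50% of genes 93.8 to 103.5). For risen genes it showed 74.5% of the rise (37.8 to 106.8). That array also had MSCs, with which 308 of the genes that fell with cytomix fell further and 40 rose. A weaker response to cytomix could thus be hidden, and on the linear scale a smaller log2 fall still gives a high share. The test also holds only if the number marks a shared culture, and AT2 cytomix 1 correlated more with control 5 (0.441) than with control 1 (0.149). RNA of unstimulated cells in the sample stays open as well, as the share of stimulated RNA was 17.3% from 166 risen genes (middle 50% of genes 7 to 26.7) and 39.7% from 149 fallen genes (3.3 to 68), a ratio of 2.29 that leaves this undecided because the ranges overlap. A shorter or weaker exposure of this culture was not tested.

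AT2 control 4 had the highest mean of interferon-inducible genes in its group (8.29, others 6.66 to 6.95) and the highest HGF (5.13, others 4.81 to 4.86). AT2 control 5 had the lowest mean of complement and antimicrobial genes (6.86, others 7.87 to 8.17), the lowest LTA4H (10.36, others 11.02 to 11.14) and the lowest CFTR (4.51, others 7.64 to 8.20). In AT2 cytomix with MSCs, array 5 had the lowest mean of antigen presentation genes (9.88, others 10.51 to 10.58) and the highest PTGIS (5.83, others 4.17 to 4.46), a gene with means of 10.28 in MSC control and 5.77 in MSC transwell. MSC transwell RNA at the share found for that array would not give this level.

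MSC transwell 1 had the lowest means of its group for complement and antimicrobial genes (6.75, others 6.99 to 7.08) and for stress response genes (8.35, others 8.93 to 9.10). MSC transwell 2 had the lowest mean of cholesterol and fatty acid synthesis genes (6.64, others 6.97 to 7.05), of LTA4H (5.91, others 8.27 to 8.52) and of CXCL9 (13.14, others 14.14 to 14.40), and the highest OCLN (3.996, others 3.42 to 3.55) and CLDN18 (4.80, others 4.24 to 4.37). No explanation of these values was tested.

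The response to cytomix differed between AT2 cells and MSCs for RGS4 by 6.48, MEST by 6.19, DEPTOR by 4.85, EVI2A by 4.83 and LAMB1 by 4.56, all of which fell in MSCs. It differed the other way for SLC39A8 by -9.09, MMP12 by -8.23, MMP10 by -7.66, HLA-DRA by -7.65 and MMP1 by -7.51. These are limma tests of the difference itself.

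Array 5 of AT2 cytomix with MSCs had high levels of genes that are bright in MSCs. MSC RNA or cells in that sample are a candidate explanation, since 9 of 9 genes bright in MSC transwell and dim in AT2 cells (CDH11, CEMIP, DEPP1, IGFBP6, MMP2, PENK, POSTN, SULF1 and VCAM1) lay above every AT2 array without MSCs, at a median share of 16.6% (middle 50% of genes 12.1 to 25.8). In arrays 1 to 4 the median shares were 0.03%, 1.83%, 0.73% and 2.62%, with 2, 6, 5 and 7 of the 9 genes above. Mesenchymal cells present in the AT2 cultures of that number are argued against by a share of -0.12% in AT2 control 5, if the number marks a shared culture. The 9 genes were chosen as dim on average over arrays that include AT2 control 5, which limits this test. A mesenchymal programme switched on in AT2 cells cannot be told apart from this, as the share was 14.2% over 6 genes outside the mesenchymal and matrix lists and 26.3% over the 3 within them, and the genes are too few. Over all genes array 5 had r of 0.9045 to 0.9299 with the MSC transwell arrays, against 0.8382 to 0.8896 for arrays 1 to 4. Either explanation could raise these correlations, so they do not decide between them.

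Genes that differed with co-culture overlapped between AT2 cells and MSCs beyond independence. Compression of the arrays by scaling is argued against as the whole cause by the correlation across genes of 0.560 after quantile normalisation, against 0.555 before. RNA crossing in both directions would move the genes of the 2 cell types in opposite directions, and 92.1% of the genes changed in both moved the same way. MSC RNA in the AT2 samples alone could carry genes raised in MSC transwell and move them the same way. The share therefore cannot speak against crossing in a single direction. Handling or RNA quality stays open, since the SD of log2 values in MSC transwell differed from MSC cytomix by -0.0223 (exact permutation p = 0.571), which decides nothing. On genes taken from the other cell type, 10 of 10 co-culture arrays scored above every cytomix array of their cell type. The scores were 0.464 to 0.738 against -0.047 to 0.045 in AT2 cells and 0.243 to 0.823 against -0.043 to 0.077 in MSCs. A response to co-culture in both cell types would give this, but the scores restate the shared difference. Handling, RNA quality or culture conditions shared by all transwells would give it as well, so the cause stays open.

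In 3 comparisons 1 of 56 splits, the real grouping, gave as many changed genes. These were MSC transwell against control (4111, highest other 750) and against cytomix (2659, highest other 957) and AT2 control against MSC control (3183, highest other 715). Chance can be excluded there only if the arrays are separate replicates, which is open for MSC control, MSC cytomix and arrays 2 and 3 of AT2 control. In AT2 cells 1 of 100 splits, again the real grouping, gave as many genes for cytomix against control (1275, highest other 348) and for cytomix with MSCs against cytomix (4363, highest other 3674) and against control (5814, highest other 1235), but these splits disregard the replicate numbers, which pair the arrays. The split with 3674 genes moves only array 4 of AT2 cytomix with MSCs across, and it parts fewer pairs of replicate numbers than the real grouping. Splits that part as many pairs number 15 here (highest other 1865), and 10 for AT2 cytomix and 11 for AT2 cytomix with MSCs against control (highest other 0 in both), which are too few for a share under 0.05. The splits with 348 and 1235 genes part fewer pairs as well. For opposite changes 1 of 100 regroupings gave as many (157, highest other 54), which decides nothing, because regroupings with few genes changed by cytomix have few to change back. For MSC cytomix against control the 10 splits are too few for a share under 0.05 (2246, highest other 0).

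For the difference of responses, 8 of 100 splits gave as many genes (1094, highest other 1862). Each of the 8 is among the 11 splits that kept the MSC groups whole or exchanged, and these still hold the MSC response. Such splits are not draws without an effect, so for genes and for lists they cannot decide about chance, which is not excluded. Counts of gene lists are less separated. Lists were counted over the same splits. As many lists were past the test in 19 of 100 splits of AT2 cytomix against control (16, highest other 20), 63 of AT2 cytomix with MSCs against cytomix (8, highest other 16), 9 against control (16, highest other 18) and 55 of the difference of responses (11, highest other 17), so chance cannot be excluded there. The same goes for 3 of 56 splits of MSC transwell against cytomix (5, highest other 5) and 8 of 56 for the controls (17, highest other 19). For MSC transwell against control 2 of 56 splits gave as many lists (12, highest other 12). That share is under 0.05, but another grouping reached the same count, so chance is not firmly excluded. For MSC cytomix against control the splits are too few (13, highest other 13, in 3 of 10).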

How the results depend on the processing

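Averaging arrays 2 and 3 of the AT2 groups, with and without the block, and repeating lists and genes without AT2 cytomix 1 or array 5 of AT2 cytomix with MSCs were chosen after the data were seen. Under all settings that left out no array, the averaging among them, 96 counts stayed within 1.5 times the reported count and 27 did not. With an array left out 73 did and 14 did not. Unless the construction of a setting is named, the cause was not tested.

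A 2-fold minimum, which can only lower counts, left 556 genes in AT2 cytomix against control, 1405 in AT2 cytomix with MSCs against cytomix and 2390 against control, 1400 in MSC cytomix against control, 2402 in MSC transwell against control and 1424 against cytomix, and 1711 for the controls. An adjusted p of 0.01 left 379 in AT2 cytomix against control, 1494 in MSC cytomix against control, 1527 in MSC transwell against cytomix and 578 for the difference of responses. Leaving out the lower 50% of genes, which tests fewer, left 2904 in AT2 cytomix with MSCs against cytomix and 3862 against control. Array weights gave 5488 in AT2 cytomix against control, 5154 in MSC cytomix against control, 4076 in MSC transwell against cytomix, 4618 for the difference of responses, 6128 for the controls and 1037 opposite changes. Fits on only the arrays compared gave 1976 in AT2 cytomix against control and 4990 in MSC cytomix against control.

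Averaging arrays 2 and 3, which leaves fewer arrays, gave 60 genes in AT2 cytomix against control (359 with the block) and 9 opposite changes (38 with the block). The block alone gave 282 opposite changes. Beside the calls printed with the results, it ended those of SLCO2A1 (0.0532) and PPARG (0.0659) in AT2 cytomix against control, CLIC5 (0.0513), PTGES (0.0614), VWF (0.0630) and TYMS (0.0549) in AT2 cytomix with MSCs against cytomix and OCLN (0.0520) against control. It added IL1RN (0.000895) and LTA4H (0.00369) in AT2 cytomix against control, and ALOX5 (0.0409) and LTA4H (0.0346) in AT2 cytomix with MSCs against cytomix. For the difference of responses it ended secreted mediators (0.0973) and 2 genes and added 4 genes. It changed no other call of a named gene or list in AT2 cells. MSC arrays of the same number shared only that number (correlations of -0.184 to 0.0782 over 9 pairs), and their counts with the block were 2263, 3855 and 2279 in the order of the comparisons. A block could not be estimated for the controls.

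Without any 1 array the counts ranged from 489 to 1913 (AT2 cytomix against control), 3823 to 4490 (AT2 cytomix with MSCs against cytomix), 5508 to 5857 (against control), 1650 to 1724 (MSC cytomix against control), 3124 to 4644 (MSC transwell against control), 1680 to 3356 (against cytomix), 792 to 1183 (difference of responses), 2497 to 3033 (controls) and 51 to 324 (opposite changes).

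With an estimated correlation 22 of the 98 lists past the test stayed so. Direction reversed for LSS in MSC transwell against cytomix with the mean over probe sets (adjusted p = 0.158), and for airway epithelial markers with fry in MSC transwell against control (7.4e-07) and against cytomix (0.0124). Quantile normalisation kept 853 values of named genes on their side of the threshold and ended 19 calls. The mean over probe sets kept 820, ended 26 and added 4, and gave smaller changes for several genes, such as COL1A1 (-3.10) in MSC cytomix, SFPQ (-1.38) in AT2 cytomix with MSCs against cytomix and SLC39A8 (-5.25) for the difference of responses. Without AT2 cytomix 1, 19 named genes of AT2 cytomix with MSCs against cytomix were no longer past the test, and without array 5, 10 were not.

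Signal over background limits dim genes, which is why the 25% with the lowest mean were left out. Alternatives with an offset before the logarithm and measures from control probe sets were not run, as the table held logarithms and 0 control probe sets.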

Other observations

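The tests of explanations reported with the arrays that stand apart are not repeated in what follows, and the transcripts of AT2 cells in MSCs were examined only after the data were seen. Single genes of amino acid and lipid metabolism changed in MSCs. In MSC transwell (n = 5) against MSC cytomix (n = 3), SLC7A11, a cystine transporter gene, fell by 3.73 and TRIB3, a pseudokinase gene of the amino acid response, by 3.33. Cytomix alone raised ACSL1, which activates fatty acids, by 5.20 and INSIG1, a brake on sterol synthesis, by 3.35, and against MSC cytomix ACSL1 fell in MSC transwell (-2.25), as did INSIG2 (-2.54). Cholesterol and fatty acid synthesis genes as a group had 4 of 28 higher and 3 lower with cytomix (median -0.21, mean 0.24, adjusted p = 0.921). Among sugar-burning genes PFKFB3 rose by 3.15 with cytomix and by a further 1.89 in MSC transwell.

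In AT2 cytomix against AT2 control, matrix, protease and protease inhibitor genes had 9 of 37 higher and 3 lower (11 and 5 adjusted over the list alone), with adjusted p = 0.00859, against 0.377 with an estimated correlation. SERPINB4, a protease inhibitor gene, rose 25.6-fold (4.68 ± 0.54) and TGM2, a transglutaminase gene, by 3.36 (2.02 as the mean over 4 probe sets). Cell death genes had 8 of 29 higher and 1 lower (8 and 2 adjusted over the list alone), with adjusted p = 0.00538, against 0.179 with an estimated correlation, and PMAIP1, a pro-apoptotic gene, rose by 2.45. Eicosanoid genes had 0 of 24 higher and 2 lower (median 0.02, mean -0.12, adjusted p = 0.720 with the direction up), and HPGD, which inactivates prostaglandins, fell by 1.72 ± 0.41. Secreted mediators attributed to MSCs had 5 of 29 higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.000402, and 0.179 with an estimated correlation), and VEGFC rose by 3.49 ± 0.55. Cholesterol and fatty acid synthesis genes had 5 of 29 lower and 0 higher (adjusted p = 0.0137, and 0.438 with an estimated correlation), with ACACA, the acetyl-CoA carboxylase gene, at -1.12 (adjusted p = 0.0690 with the mean over probe sets).

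Basal cell keratins were not past the test in AT2 cytomix against AT2 control, with KRT5 at -2.59 ± 1.06 (adjusted p = 0.113) and KRT14 at -2.22 (adjusted p = 0.226). Without AT2 cytomix 1 they had -3.97 (adjusted p = 0.00144) and -3.57 (adjusted p = 0.0170). LYZ, the lysozyme gene, stood at 11.88 and 12.06 in AT2 control 2 and 3 and at 3.85 to 8.59 in the other controls, and at 11.53 and 11.48 in AT2 cytomix 2 and 3 and at 7.09 to 7.57 in the others. It is named by the list rule, and its pattern over arrays was noticed after its values were seen.

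In MSC transwell, 13 genes bright in AT2 cells and dim in MSCs lay above every MSC array without AT2 cells in 3, 7, 6, 8 and 4 cases in arrays 1 to 5 and corresponded to median AT2 shares of -0.13%, 0.56%, 0.13%, 1.29% and 0.27%. SFTPB, SFTPC, EPCAM and SLPI were among them. PDZK1IP1 had a mean of 7.67 in MSC transwell and of 4.74 in MSCs without AT2 cells.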
